A study of Homo sapiens with 3 samples.

How the data were processed

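The data are DNase-seq peak lists from SKBR3, a human breast cancer cell line known for its high level of HER2, the receptor tyrosine kinase encoded by ERBB2. DNase-seq digests nuclei with DNase I and sequences the ends of the released fragments, so that places where the enzyme cuts often (DNase I hypersensitive sites) appear as piles of reads. The series holds 3 libraries of 1 group, named replicates 1, 2 and 3 after their titles. The labels do not say whether the replicates came from separate cultures, so the spread between them may be technical. There is no second cell type, treatment or control library in this series, and no contrast between groups was made.

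The submitters' processing notes name CASAVA 1.3, BWA, bedtools and MACS2 and the human genome build hg19, without roles or order. The MACS2 version and options, the read filters, the effective genome size and any control are not given in the sources used here. Each library has 1 deposited peak list of its own, in narrowPeak layout, with peaks numbered without a gap. Start, end and summit offset are positions in bp. The deposited score is the −log10 q value times 10 cut to a whole number, which held for a mean of 99.997% of peaks. The deposited signal value is a fold enrichment (a ratio of reads to expected reads at the summit), and the 2 further columns are deposited as −log10 of the p-value and −log10 of the q-value. These are the authors' values for each peak. They describe and rank peaks within a list, and a value of the same region is set beside that of another list only as a measure of replicate spread.

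The deposited fold and −log10 p together gave back the reads behind each peak. With m whole reads over the summit and an expected number of reads L, the fold equals (m + 1) / (L + 1) and p is the upper Poisson tail of m given L. A whole number m and a value L that gave the deposited −log10 p within 0.0001 existed for 100% of the peaks in all 3 lists. L was either 1 genome-wide value per library or, in all other peaks, a multiple of 0.02 (L divided by 0.02 lay within 0.02 of a whole number). L is called the local background here. It is taken here to be set by the reads of the same library in a window around the summit, which the sources do not state. It never lies below the genome-wide value, so lower read densities cannot be seen. The step of 0.02 is what a read extension of 200 bp and a window of 10 kb would give. Neither length is stated in the sources used here. The genome-wide value was 2.19, 2.18 and 2.15 expected reads in replicates 1, 2 and 3, so the depths differed by at most a factor of 1.02. With an assumed effective genome size of 2.7 Gb and the 200 bp extension it would correspond to 29.6 M, 29.5 M and 29.0 M reads. The totals themselves are unknown, and duplicate handling is not given, so counting error at a summit may be larger than Poisson.

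Peaks of the 3 lists that overlapped by at least 1 bp were joined into union regions. A region with a peak in every list is called shared. Where a list had several peaks in a region, its strongest peak by fold gave the values. Overlap between lists was the percentage of peaks of 1 list that overlapped a peak of another, over 6 directed pairs, and the Jaccard index over bases. The level expected by chance came from 100 circular shifts of the lists of replicates 2 and 3 along each chromosome, between its first and last peak. Recovery by strength was the percentage of peaks found in both other lists per decile of fold. Shared regions were counted in 768 tiles of 4 Mb on chromosomes 1 to 22 and X. The tile from 36 to 40 Mb of chromosome 17 was fixed before the data were examined, because the series concerns screens of regulatory elements and the related study screened around HER2. That the tile holds ERBB2 is textbook knowledge of its hg19 position and not the result of an annotation. The plan also held, as prior knowledge, that SKBR3 carries extra copies of this region and that copy number raises signal. Local background was summarised per tile as the median over shared regions divided by the genome median of the same library, as mean and SD over 3 replicates, for tiles with at least 10 shared regions. Isolated regions are those with no other union region within 5 kb of the summit, and their ratios are to the median of all isolated shared regions unless another divisor is named. A high-background segment is a run of 1 Mb tiles with at least 3 shared regions each and a ratio of 2 or more in all 3 replicates. The use of local background, the segments and the isolated regions were chosen after the data had been seen. Relations across tiles are Spearman and Pearson correlations with 2-sided p-values from all circular shifts of the tile order, adjusted by Benjamini-Hochberg over the 5 relations computed.

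Regions are named by rules fixed before the data were examined: the 10 shared regions with the highest mean fold, the 10 tiles with the most shared regions and the 10 shared regions of the chromosome 17 tile with the highest mean fold. Regions ranked by summit reads, windows of 100 kb and segment edges were added after their values were seen. The only gene table at hand is of build GRCh38, so no gene, promoter, exon or motif was assigned to hg19 positions. The planned comparisons of promoters with distal regions, of gene lists, of genomic annotation and of sequence motifs, and the adjustment of tile counts for transcription start sites, were not run. Alternatives were the overlap rule, the peak threshold, the list size, the tile size, summed length in place of number, and leaving out each replicate. Coordinates are 1-based in hg19. The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots used matplotlib 3.10.9. On simulated data the recovery returned the reads of 100% of 58746 simulated peaks, the joining of lists found 100% of 2942 simulated shared regions, and a tile simulated at 3 times the background came out at 2.91.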

Results

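DNase I hypersensitive sites of SKBR3 breast cancer cells were mapped in 3 replicate libraries. The peak lists held 65957, 64103 and 64665 sites in replicates 1, 2 and 3, a mean of 64908 ± 951 (SD, n = 3). They covered 22.5 ± 0.384 Mb of the genome, with a median width of 301 ± 1.15 bp and a shortest peak of 200 bp. The median fold enrichment at the summit was 6.98 ± 0.0467 and the median number of reads over the summit was 34 in every replicate. The lowest −log10 q was 2.71, 2.62 and 2.61, and the highest fold was 29.8, 29.2 and 31.1. All peaks lay on chromosomes 1 to 22 and X.

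The first comparison was between the replicates, which asks which sites are open reproducibly in these cells. Most sites were found again: 51047 regions had a peak in all 3 lists, 65.2% of the 78258 union regions, and covered 22.2 Mb. A further 11268 regions (14.4%) had a peak in 2 lists and 15943 (20.4%) in only 1. Peaks of one list overlapped a peak of another in 85.8% ± 0.883 of cases (SD of the 3 replicates' means), between 84.7% and 87.3% over the 6 directed pairs. Circularly shifted lists overlapped in 1.73% of cases on average and in at most 1.84% in 100 shifts, and gave 36.03 shared regions on average and at most 57. The Jaccard index over bases was 0.697, 0.696 and 0.691 for the 3 pairs, against 0.00450 in shifted lists.

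Shared regions were wider and stronger than the others. Their median width was 378 bp, their median fold 7.81 and their median number of summit reads 39.7. Regions in 2 lists had medians of 267 bp, 5.34-fold and 21.5 reads, and regions in 1 list had medians of 216 bp, 4.83-fold and 19 reads. The numbers of regions found in replicate 1, 2 or 3 alone were 5785, 4923 and 5235, and their median folds were 4.86, 4.85 and 4.79. The width of a joined region grows with the number of lists joined, which adds to the difference in width.

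Recovery rose with strength in all 3 lists. In the weakest decile by fold, 44.5% ± 3.18 of peaks (SD, n = 3) were found in both other lists. The figure was 83.0% ± 1.47 in the fifth decile and 96.4% ± 0.502 in the seventh. In the ninth decile it was 99.8% ± 0.0786, and every peak of the strongest decile was found in both other lists of all 3 replicates. The difference between the strongest and the weakest decile was 55.5 ± 3.18 percentage points. An exact sign-flip permutation test over 3 replicates cannot go below p = 0.25, two-sided, so no p-value is given. Only 471 of the 15943 regions found in 1 list (2.95%) had a fold above the median of that list.

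**Figure D1:**
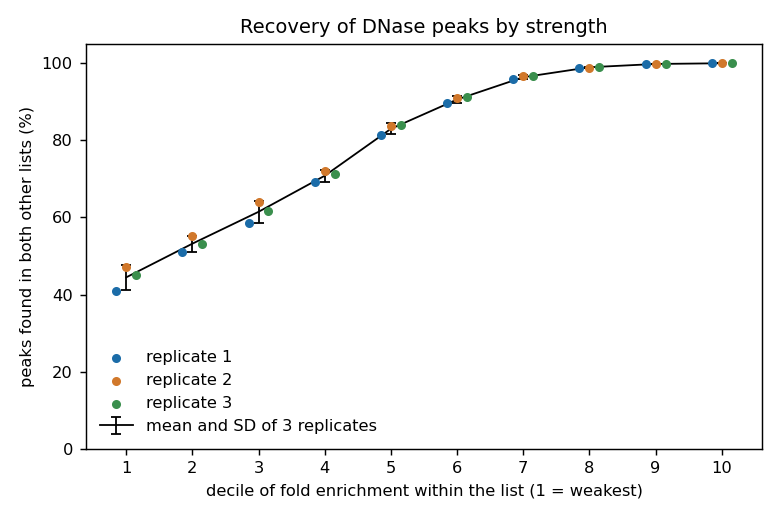
The percentage of peaks found in both other lists (vertical axis) is plotted by decile of fold enrichment within each list (horizontal axis, 1 the weakest). Points are the 3 replicates and the line with bars is their mean and SD, which runs from 44.5% in the first decile to 100% in the last.

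Within the shared regions the libraries ranked sites alike. The Spearman correlation of summit reads across the 51047 regions, which are not independent replicates, was 0.918 for replicates 1 and 2, 0.923 for 1 and 3, and 0.911 for 2 and 3. The same correlations for fold were 0.884, 0.877 and 0.877. The 3 summits of a region lay a median of 31 bp apart. The lists were not copies of each other. In 4600 regions whose summits lay within 10 bp and whose local background was above 3 reads in every list, the reads in the local window gave a mean chi-square per region of 1.47 ± 0.0333 (SE) for replicates 1 and 2, 1.18 ± 0.0250 for 1 and 3, and 2.08 ± 0.0504 for 2 and 3. Poisson counting alone would give a mean of 1. Counting error may be larger than Poisson here, so the excess is not a measure of differences between cultures.

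The 10 strongest shared sites by fold lay outside the segments of raised background described below. Those segments held only 4.53% of shared regions and were selected for a high background, the denominator of fold. Their absence from the 10 therefore says little about where strong sites lie. The highest mean fold was 29.5 ± 1.81 (SD, n = 3) at chromosome X from 136520314 to 136520646, with 112 ± 5.86 reads over the summit. The second was 28.9 ± 1.12 at chromosome 6 from 119558474 to 119558780, with 171 ± 10 reads. These 2 regions stood apart from the third, at chromosome 12 from 95397143 to 95397726, which had a fold of 22.9 ± 1.47. The other regions of the leading 10 had mean folds between 21.1 and 22.5. They lay on chromosome 1 from 713878 to 714393, on chromosome 6 from 31774499 to 31774951 and from 34393714 to 34394084, on chromosome 11 from 62528801 to 62529331, and on chromosome 19 from 13029966 to 13030378, from 13842320 to 13842729 and from 45273781 to 45274193. No gene was assigned to these positions, because no annotation of the build was used.

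Sites were unevenly spread over the chromosomes. Chromosome 19 was the densest with 44.3 shared regions per Mb between its first and last peak, followed by chromosome 17 with 34.1, chromosome 22 with 33.8 and chromosome 20 with 32.8. The density was lowest on chromosome X with 6.48, chromosome 4 with 8.03 and chromosome 18 with 8.53, against 17.3 over all chromosomes. Chromosome 19 also had the largest share of its union regions in all 3 lists, 75.7%, and chromosome 4 the smallest, 57.6%. Of the 768 tiles of 4 Mb, 729 held at least 1 shared region, and the median tile held 53.

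The 10 tiles with the most shared regions came from 5 chromosomes. The leading tile was 44 to 48 Mb of chromosome 19 with 309 shared regions, and 3 more tiles of that chromosome, from 0 to 4, 16 to 20 and 48 to 52 Mb, held 278, 262 and 277. The tile from 64 to 68 Mb of chromosome 11 held 295. Chromosome 17 had 3 of the 10 tiles, with 286 regions from 76 to 80 Mb, 280 from 36 to 40 Mb and 276 from 72 to 76 Mb. Chromosome 16 from 0 to 4 Mb held 261 and chromosome 20 from 48 to 52 Mb held 257.

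The tile from 36 to 40 Mb of chromosome 17, which holds the HER2 locus, was the region of interest fixed beforehand. It had rank 4 of 768 tiles with 280 shared regions, 5.28 times the median tile and more than 99.6% of the other tiles. The replicates had 342, 342 and 347 peaks in it. Of its 408 union regions 68.6% were shared. Its sites carried many reads but moderate folds: the median was 80 summit reads against 39.7 over all shared regions, and the median fold was 5.64 against 7.81. The tile held 0.549% of all shared regions. It supplied 81 of the 1000 regions with the most summit reads, where its share of regions would give 5.49, and 2 of the 1000 regions with the highest fold. When only the strongest 20000 peaks by fold of each list were used, the tile held 47 shared regions against a median tile of 15, and ranked 68th.

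By mean fold, the leading site of this tile was at 36452771 to 36453259, with 17.96 ± 0.555 (SD, n = 3). The next were at 36412989 to 36413631 with 16.6 ± 1.39, at 38358090 to 38358525 with 16.5 ± 0.318, at 37123580 to 37124023 with 16.5 ± 1.66, and at 39992065 to 39992696 with 14.96 ± 0.541. These differences among the second, the third and the next were smaller than the spread between replicates. The remaining 5 of the leading 10, at 36874792, 37009870, 37606974, 38375268 and 38959807 (start positions), had mean folds between 13.6 and 13.8. The sites at 36412989, 36452771, 36874792, 37009870 and 37123580 lay before position 37213583, after which the background rises as described below. Between 2.21 and 3.52 reads were expected at them, against at least 6.96 at the others of the leading 10. The ranking by reads, added after the values were seen, gave other sites. The most summit reads were 313 ± 14.6 at 37333451 to 37334025, 290.3 ± 8.14 at 37606974 to 37607810 and 288 ± 9.87 at 37879618 to 37880346. A wide region at 37557543 to 37559068 had 273 ± 9.54 reads, and the region at 37843915 to 37844680 had 260 ± 1.53. The site at 37861998 to 37862688 had 255 ± 15.1 reads, and its fold was only 4.83 ± 0.129 because 52.1 ± 4.31 reads were expected there.

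The local background, the number of reads expected at a summit from the reads around it, was raised in segments of 1 to 12 Mb, in all 3 libraries. Over all shared regions its median was 4.12 reads. In the chromosome 17 tile it was 3.16 ± 0.0392 times the genome median (SD, n = 3), rank 4 of 667 tiles. The highest was 4.87 ± 0.0443 times, from 120 to 124 Mb of chromosome 8. All 3 replicates exceeded 2 times the genome median in 17 tiles (2.55%), 8 of them on chromosome 8, 5 on chromosome 20, and 2 each on chromosomes 7 and 17. Among whole chromosomes, chromosome 20 had the highest ratio with 1.84 ± 0.0230, followed by chromosome 7 with 1.33 ± 0.00373. The lowest were chromosome 4 with 0.686 ± 0.0168, chromosome 18 with 0.689 ± 0.00806 and chromosome X with 0.699 ± 0.00924. With isolated regions over the isolated median, chromosomes 20 and 7 stood at 1.75 and 1.37, and chromosomes 4, 18 and X at 0.738, 0.734 and 0.768. The window also holds the reads of the peak and of its neighbours. Isolated regions had a lower median over the genome, 3.33 reads. Divided by that median, the isolated regions stood at 2.36 ± 0.0564 in the chromosome 17 tile (81 regions) and 5.63 ± 0.0720 in the chromosome 8 tile (75 regions). Divided by the median of all shared regions, as the other ratios are, they stood at 1.91 ± 0.0279 and 4.56 ± 0.0284. On the isolated scale the chromosome 17 tile fell below tiles ranked under it over all shared regions. Among them were chromosome 8 from 116 to 120 Mb at 3.62 and chromosome 20 from 52 to 56 Mb at 2.75. With isolated regions, 15 of the 17 tiles exceeded 2 times the isolated median in all 3 replicates, but only 6 exceeded 2 times the median of all shared regions, the divisor by which the 17 were counted. Below 2 on both scales were the chromosome 17 tile from 76 to 80 Mb, at 1.85 ± 0.0368 times the isolated median, and the chromosome 8 tile from 128 to 132 Mb, at 1.33 ± 0.0295. Within the latter, the 16 isolated regions from 128 to 129 Mb stood at 5.23 ± 0.164.

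**Figure D2:**
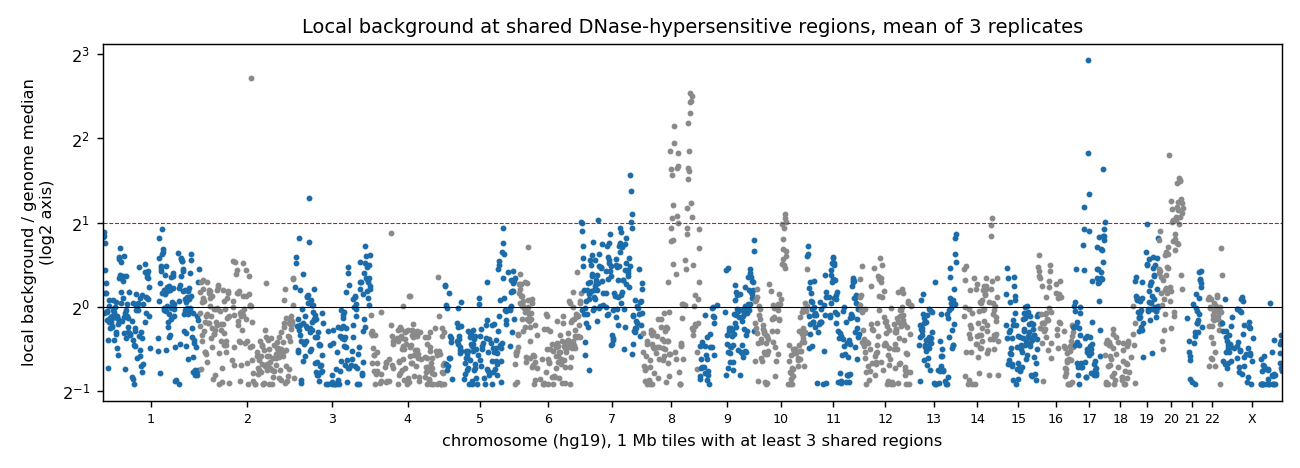
Each point is a 1 Mb tile with at least 3 shared regions along chromosomes 1 to 22 and X, and the vertical log2 axis is its local background divided by the genome median, as the mean of 3 replicates. The dashed line is a ratio of 2, which 52 of 2329 tiles reach in all 3 replicates, and the highest points are on chromosomes 17, 2, 8 and 20. With isolated regions the chromosome 2 tile, from 133 to 134 Mb, falls to 0.863 times the isolated median. The chromosome 20 tile from 26 to 27 Mb, at 3.48, rests on only 4 shared regions.

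At 1 Mb resolution, 52 of 2329 tiles (2.23%) reached 2 times the genome median in all 3 replicates and formed 25 segments, 10 of them at least 2 Mb long. The longest was 12 Mb, from 115 to 127 Mb of chromosome 8, with 445 shared regions and a ratio of 3.80 ± 0.102 (SD, n = 3). On the same chromosome the tile from 128 to 129 Mb reached 5.65 ± 0.00994, the segment from 80 to 82 Mb 4.24 ± 0.189 and the segment from 88 to 92 Mb 3.14 ± 0.0778. Chromosome 20 had 8 segments, of which the longest, from 54 to 58 Mb, had a ratio of 2.69 ± 0.0678. Its segment from 26 to 27 Mb, at 3.48 ± 0.122, rested on only 4 shared regions. The 2 isolated ones there stood at 1.68 ± 0.117 times the isolated median. The segment from 37 to 40 Mb of chromosome 17 had a ratio of 3.41 ± 0.1002. Its tile from 37 to 38 Mb, with 82 shared regions, stood at 7.62 ± 0.204, the highest in the genome over all shared regions. With isolated regions alone it stood at 6.13 times the isolated median, below the chromosome 8 tiles from 121 to 122 Mb (7.06) and from 123 to 124 Mb (6.42). The neighbouring tiles stood at 0.706 ± 0.00552 from 36 to 37 Mb, 3.54 ± 0.0678 from 38 to 39 Mb and 2.53 ± 0.151 from 39 to 40 Mb. In the tile from 133 to 134 Mb of chromosome 2 the ratio was 6.56 ± 0.313 over 24 shared regions but 0.863 ± 0.0421 over the 6 isolated ones, relative to the isolated median. Of the 52 tiles, 40 also reached the limit with isolated regions alone on that scale, and 26 when isolated regions were divided by the median of all shared regions.

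The background changed over a short distance near the 4 segment ends examined, which were chosen after the data had been seen. On chromosome 17 the median local background of the 10 shared regions up to position 37213583 was 2.60 reads, and that of the 10 regions from position 37279835 onward was 38.002 reads, a step of 14.6-fold across a gap of 66.3 kb. The step was present in each library, from 2.72 to 38.3 reads in replicate 1, from 2.56 to 38.4 in replicate 2 and from 2.55 to 37.5 in replicate 3. These medians include regions with close neighbours, whose reads add to the local background. The value before the step also lies near the genome-wide value, below which nothing can be seen. With isolated regions the tile from 36 to 37 Mb stood at 0.768 times the isolated median and the tile from 37 to 38 Mb at 6.13 times. The background fell again between 40541025 and 40550458, from 9.48 to 3.93 reads, which lies beyond the segment from 37 to 40 Mb. Before that, the tile ratio declined from 7.62 at 37 to 38 Mb to 2.53 at 39 to 40 Mb. The tile from 40 to 41 Mb, with a ratio of 1.87 and of 1.27 with isolated regions over the isolated median, spans the fall. On chromosome 8 it fell 4.26-fold between 126619084 and 126646057, and 8.32-fold between 129103692 and 129121148. The longest segment of chromosome 8 began gradually, with ratios of 1.37, 1.82, 1.91, 2.27 and 4.56 in the 1 Mb tiles from 112 to 117 Mb.

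**Figure D3:**
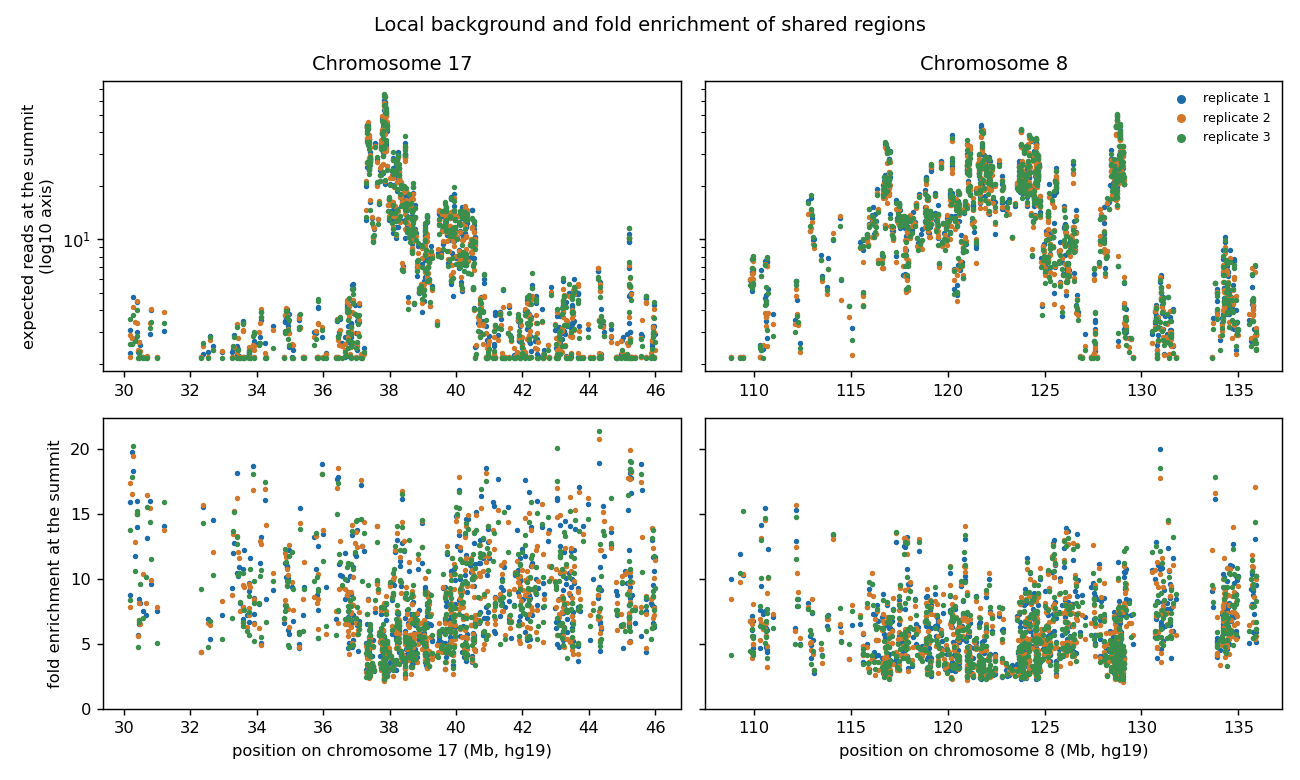
Expected reads at the summit (top, log10 axis) and fold enrichment (bottom) of each shared region are plotted against hg19 position on chromosomes 17 (left) and 8 (right), with 1 colour per replicate. The background of the 3 replicates rises together after position 37213583 of chromosome 17, from 2.60 to 38.002 reads, and ends on chromosome 8 after position 129103692, while fold shows more low values inside the segments.

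Sites inside the segments differed from those elsewhere in reads and in fold. The 2311 shared regions of the 25 segments had a median of 73 ± 1 summit reads (SD of the 3 replicates' medians), against 38.7 ± 1 in the other 48736. Their median fold was 5.75 ± 0.0337, against 7.89 ± 0.0778. The segments were selected for a high background, which enters the fold as its denominator. More reads and a lower fold inside them may therefore follow from the selection, and how much does was not tested. The share of union regions found in all lists was 64.1% inside the segments and 65.3% outside. Across 663 tiles with at least 10 shared and 5 isolated regions, the number of shared regions rose with the background of isolated regions (Spearman's rho 0.62, Pearson's r 0.45). The permutation p was 0.0015, the smallest that the circular shifts can give, and 0.0015 after adjustment over 5 relations. Tiles are not independent replicates. Without chromosomes 8, 17 and 20 rho was 0.64 over 592 tiles.

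**Figure D4:**
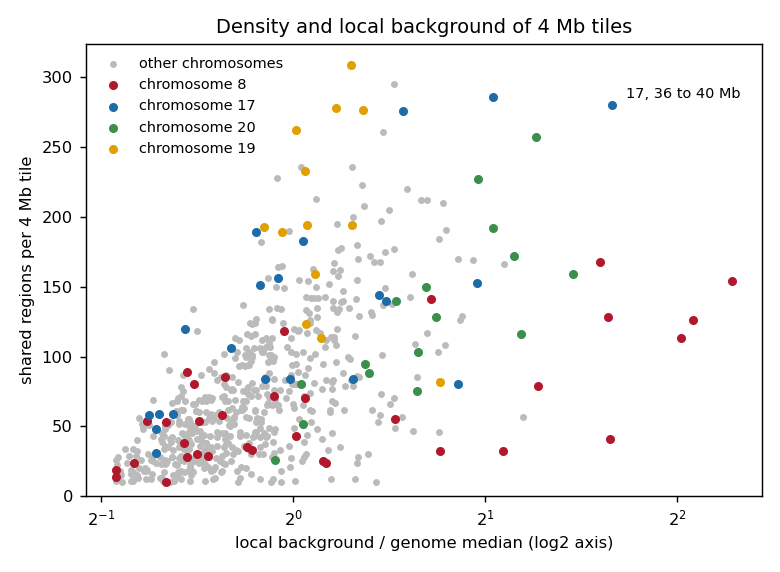
The number of shared regions (vertical axis) is plotted against local background relative to the genome median (horizontal log2 axis) for 4 Mb tiles with at least 10 shared regions, coloured by chromosome. Tiles of chromosome 19 reach 309 regions near the genome median, while the labelled tile of chromosome 17 combines 280 regions with a ratio of 3.16.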

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

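The chromosome 2 tile from 133 to 134 Mb reversed, from 6.56 times the genome median to 0.863 times the isolated median with isolated regions. The alternatives for recovery by strength, local background and segments, the thinning of reads, and leaving out a replicate for the overlap were chosen after the data had been seen. With a reciprocal overlap of 50%, the overlap was 83.1% and the strongest and weakest deciles differed by 61.7 percentage points; with summits within 100 bp these were 81.3% and 63.5 points. The strongest 20000 peaks per list gave an overlap of 83.2%, 15173 shared regions, a decile difference of 68.6 points and a percentile of 90.7 for the chromosome 17 tile. A −log10 q of at least 5 gave 52.0 points and a percentile of 99.2, and equal list sizes gave 59.6 points. The tile's percentile was 97.3 for the 2 Mb tile from 36 to 38 Mb, 99.5 for the 1 Mb tile from 37 to 38 Mb, 99.9 by summed length and, after thinning at a −log10 p of at least 10, 94.8 with factors per 1 Mb and 95.96 per 4 Mb, or 96.1 and 97.0 with a correction for a ceiling on reads. The background ratio of the chromosome 17 tile was 2.36 with isolated regions, 1.91 with isolated regions over the median of all shared regions, 2.47 after subtracting summit reads, 3.46 as a mean, 5.84 in the 2 Mb tile and 7.62 in the 1 Mb tile. For the chromosome 8 tile the first 4 were 5.63, 4.56, 6.64 and 4.12. A limit of 1.5 or 3 times gave 144 or 21 high-background tiles of 1 Mb, and isolated regions over the median of all shared regions gave 26. Leaving out 1 replicate gave overlaps of 85.6% to 86.0%, 54416 to 55442 shared regions and decile differences of 41.2 to 42.3 points, where only 1 other list had to hold the peak. It gave percentiles of 99.3 to 99.7, ratios of 3.17 to 3.20 on chromosome 17 and 4.82 to 4.94 on chromosome 8, and 51 to 60 high-background tiles. For the other shifts the cause was not tested. Total depth is unknown, and a local background below the genome-wide value cannot be seen. Weak sites may be limited by depth, which was not tested. At the median of 19 summit reads, a region missing from a list is not shown to be closed. No paired analysis was possible because the series has 1 group.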

Other observations

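The densest clusters of open sites in these cells lay both in and outside the segments of raised background. Of the 15 windows of 100 kb with the most shared regions, 7 lay in a segment and 8 outside. The segments held 4.53% of all shared regions and 2.23% of the 1 Mb tiles with at least 3 shared regions. Reads of neighbouring sites add to the local background in such dense windows, and the segments were chosen by that background. More of the 15 windows in segments than these shares would give may therefore follow in part from the selection. Of all windows of 100 kb, the one with the most shared regions was on chromosome 17 from 37800001 to 37900000, with 23 sites at a median fold of 3.77 and a median background 10.8 times the genome median, where the median occupied window held 2 sites. By its textbook hg19 position the HER2 gene lies in this window; no annotation was used to place it. Next came chromosome 20 from 48700001 to 48800000, in a segment, with 19 sites at 2.62 times the genome median. Chromosome 11 from 64000001 to 64100000, outside the segments, held 18 sites at 2.18 times. A second window of the chromosome 17 segment, from 37300001 to 37400000, held 18 sites at 8.61 times the genome median. Windows on chromosome 8 from 128800001 to 128900000 and from 124500001 to 124600000 held 17 and 16 sites at 7.20 and 6.95 times. The 8 windows outside the segments had 1.51 to 3.55 times the genome median, so some of them also passed a ratio of 2. Chromosome 16 from 2000001 to 2100000 held 16 sites at a median fold of 8.69 and 1.64 times the genome median. Chromosome 1 from 1200001 to 1300000 held 15 sites at 8.16-fold and 1.91 times.

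A few sites were strong in 1 list and absent from the other 2. The strongest was on chromosome 5 from 43074076 to 43074331 in replicate 2, with a fold of 10.2 and 34 summit reads. The next were on chromosome 16 from 71401355 to 71401634 and from 82401627 to 82401883, both in replicate 2 with a fold of 10.1 and 31 reads. Regions of 1 list with a fold above that list's median numbered 163, 160 and 148 in replicates 1, 2 and 3.

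Among the tests given from here on, those of neighbouring peaks, of the peak's own reads, of the number of sites with factors per 4 Mb tile and of the ceiling had their limits set before their own results were seen, that of the ceiling after the thinned values without it. Their other forms, and the tests of segment gain, of openness per copy and of weaker added peaks, were chosen or given their present form after a related result had been seen. The segment test was first run on the isolated shared regions that had defined the segments (86.4% on chromosome 17) and was replaced for that reason. Extra copies of any kind were at first set aside on the thinning per 4 Mb tile; the explanation was then narrowed to copies as open as the rest, and factors per 1 Mb were added. The raised background on chromosomes 17 and 8 was weighed first. Reads of neighbouring called peaks do not account for all of it in the tiles tested. Isolated regions had at least 2.33 times the median of all isolated regions in both tiles and all 3 replicates. Relative to all shared regions it was at least 1.88 times. Such reads may account for part of it on chromosome 17, where the ratio fell from 3.16 to 1.91 on 1 divisor. The chromosome 8 tile from 128 to 132 Mb, which was not tested, fell from 4.24 to 1.33 times the isolated median. Reads over the summit do not account for all of it either, since the lowest ratios were 2.33 and 1.85 after they were subtracted. Reads elsewhere in a wide peak were not subtracted. A gain of whole segments in this line stays open as a candidate explanation. The plan took extra copies of the HER2 region in SKBR3 as prior knowledge, but no copy number was measured here. Of the isolated sites in only 1 or 2 lists, 94.6% (35 of 37, exact 95% interval 81.8% to 99.3%) on chromosome 17 lay above the genome's 75th percentile for such sites. On chromosome 8 it was 98.5% (195 of 198, 95.6% to 99.7%). The intervals take sites as independent, but sites of 1 segment share a regional background, so they are likely too narrow. These sites also share the surrounding reads by which the segments were chosen, so any regional cause would give this. Whether any extra copies would each be as open as the rest of the genome also stays open: after thinning per 4 Mb tile the 90th percentile of fold stood at percentile 1.53 of tiles on chromosome 17 (0.613 to 5.21 over 100 draws) and 0.153 on chromosome 8, but it was 7.03 on chromosome 17 with factors per 1 Mb, and a ceiling on reads would move both. On chromosome 8 this thinning left only 32 of 129 shared sites at a −log10 p of at least 10, so its percentile rests on few sites.

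The second pattern is the high number of shared sites around HER2. Extra reads let weaker sites pass the authors' threshold, so the reads of each tile above the genome median were thinned by its ratio (of isolated regions to the isolated median, or of all shared regions where fewer than 5 were isolated), and sites had to reach a −log10 p of 10 in all lists. The tile's percentile then went from 99.5 to 95.96 (95.2 to 97.0 over 100 draws) with factors per 4 Mb, and to 97.0 (96.1 to 97.4) with the ceiling correction described below. Factors per 1 Mb were added because the background ratio within the tile ranged from 0.706 to 7.62, which a single factor does not match. They gave 94.8 (93.2 to 95.6), and 96.1 (95.4 to 96.9) with the correction. Before thinning the tile held 260 such sites, at rank 5. Thinning left 155 with factors per 4 Mb and 139 with factors per 1 Mb, or 171 and 161.5 with the correction. Its ranks were then between 23 and 40 over the 4 forms, and single draws gave ranks from 20 to 50. The median tile held 45 before thinning and 43 to 45 after it, so thinning removed part of the excess. None of the 4 forms brought the percentile below the limit of 90 set for extra reads as the whole cause. But 1 of them crosses the limit of 95 for excluding it, so this stays open. So does the number of genes in the tile, which was not used here.

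The third pattern is the lower fold in the high-background segments, which were selected on the denominator of fold. Weaker peaks added by extra reads stay open in both tiles. After thinning per 1 Mb, the 90th percentile of fold on chromosome 8 stood at percentile 0.153 of tiles (at most 0.612 over 100 draws). This was below the limit of 5, but with a correction for a ceiling some draws passed that limit. Thinning left 31 of the 129 shared sites of that tile, or 44 with the correction. Its 90th percentile of fold therefore rests on few sites. On chromosome 17 the percentile was 7.03 (3.66 to 13.6). A ceiling of 1 kept read per position and strand, which would allow at most 400 reads over a summit for a 200 bp extension, is a possible explanation: the highest number in any list was 329, and a correction for it moved the percentiles to 26.7 (17.7 to 35.5) on chromosome 17 and 6.72 (0.916 to 19.4) on chromosome 8 with factors per 1 Mb, and to 14.7 (9.79 to 24.3) and 3.52 (0.306 to 12.8) with factors per 4 Mb. The chromosome 8 ranges cross the limit of 5, and duplicate handling is not given in the sources used here, so the ceiling stays open, and openness per copy was not measured.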
